A study of Homo sapiens with 36 samples.

How the data were processed

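Per the submitters' processing notes, the reads were quantified with Salmon, whose version is not given in the sources used here, and the deposited tables hold one library each. The notes name the mouse build mm10, but every transcript identifier in the deposited tables is a human Ensembl identifier. The authors' estimated counts, the number of reads that Salmon assigned to each transcript (expected counts), were the values analysed. The deposited TPM (abundance scaled by Salmon to transcript length and depth) served only to check the tables, since recomputing them from the estimated counts and effective lengths differed by at most 0.0009 as a fraction. The deposited effective lengths entered only the alternative with length offsets.

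Of 177456 transcripts in each table, 174542 (98.36%) matched a gene of GENCODE v29 on GRCh38, of which 7515 matched only through the annotation's HGNC table, mostly copies on alternate haplotypes. These gave 35360 genes and held 98.9% to 99.3% of the reads of each library. Estimated counts were summed per gene and rounded. The libraries of each kit were fitted on their own, with all groups of the kit in 1 model and each comparison a contrast of group means. Genes with too few reads for any group were removed by filterByExpr of edgeR, counts were scaled by TMM, and the quasi-likelihood F-test of edgeR with robust dispersions gave p-values, adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. All p-values for genes and every change given as log2 are from this test unless another is named. The standard error of a log2 change is its size divided by the square root of F. The common biological coefficient of variation was 0.206 in the poly(A) libraries and 0.0522 in the ribosomal RNA-depleted ones. CPM use the TMM-scaled library sizes.

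Before the data were examined, 37 gene lists for pathways, brain regions and cell types were written from general knowledge, and the groups, the 17 comparisons, the tests, the alternatives and the naming rule were fixed. Each list was tested with camera of limma at the preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. With fry, which asks only whether the members of a list move one way on balance, 310 of 629 tests passed. Genes named are the 5 largest rises and 5 largest falls of a comparison (adjusted p under 0.05, mean of at least 3 log2 CPM, an official symbol, no overlap between the libraries of the groups except in interactions), up to 3 members per list with the smallest adjusted p (2 where none passed), and a fixed set of readout genes. Some genes that this rule picked, and tests that rest on them, are not reported here. Chance separates 3 libraries from 3 others in 10% of genes. A group with 0 reads allows up to 3 counts per library, so no fold change was given against such a group.

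Alternatives were DESeq2 with its Wald test, DESeq2 size factors in edgeR, no filter on low counts, a stricter filter (at least 1 CPM in 3 libraries and a mean of at least 2 CPM), offsets from effective transcript lengths, only the groups compared in the fit, the replicate number as a block, and each library left out in turn. Where a group kept 2 libraries, its spread was taken from the pooled fit. Calling was tried on simulated counts with the size and spread of these libraries and 200 genes planted with a change. For CHIR against no factor at DIV50 (17051 genes), edgeR recovered 20.9% of genes planted at 1.5-fold, 68.7% at 2-fold and 66.7% at 4-fold. Of its 108 calls, 4 were false (3.7%), and 14.9% with DESeq2. For DAPT on Lam511 at DIV30 (17075 genes), it recovered 70.1%, 77.6% and 93.9%. Of its 174 calls, 13 were false (7.5%, above the 5% aimed at), and 8% with DESeq2. Of 100 random lists per simulated comparison, 1 to 7 had a camera p under 0.05. Random lists leave lists of correlated genes untested.

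The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.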

Results

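RNA was profiled in cultures derived from ATCC DYS0100, an established line of human induced pluripotent stem cells (hiPSC), during differentiation toward hippocampal dentate gyrus neurons. The dentate gyrus is the part of the hippocampus in which granule neurons keep being added from neural stem cells. The title of the series names external factors and neurogenesis, and the labels give 2 of them: CHIR99021 (CHIR, 3 µM), which inhibits the kinase GSK3 and so raises Wnt/β-catenin signalling, and DAPT (12.5 µM), which inhibits γ-secretase and so blocks Notch receptor activation. The protocol given with the samples has CHIR in the medium from DIV16 (DIV, day in vitro) until differentiation starts, for all differentiated groups alike. By that protocol every DIV28 and DIV50 group had met CHIR earlier, yet DIV28 and DIV50 without factors are labelled with treatment None. Whether None covers that medium is not given. The 36 libraries form 12 groups of 3. A poly(A) kit (SMART-Seq) gave 24 libraries: undifferentiated hiPSC, DIV28, DIV50 without factors, DIV50 with CHIR, DIV50 with DAPT, DIV50 with CHIR+DAPT, DIV174 with CHIR and DIV174 with CHIR+DAPT. A ribosomal RNA depletion kit gave 12 libraries at DIV30, after 48 h on a coating labelled Lam511 or Msl, each with CHIR or with CHIR+DAPT. What Msl stands for is not given, and levels were never compared between the kits.

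Each poly(A) library held 9.55 M to 34.0 M estimated reads (median 19.04 M), and each ribosomal RNA-depleted library 35.4 M to 48.3 M (median 41.2 M). All 24 and all 12 pairs of libraries within a group differed by more than sampling noise, so none is a copy of another. The p-values measure only the spread between these libraries, because the labels do not say whether replicates were separate cultures. One library, replicate 1 of DIV174 CHIR+DAPT, had the highest share of reads in its 10 most abundant genes (7.93%, against a median of 6.27% over the 24 libraries). edgeR tested 17560 genes in the poly(A) libraries and 17399 in the others. Levels are in CPM (counts scaled to a common library size), given as mean ± SD with n = 3 libraries in each group throughout, and log2 changes carry their standard error. Numbers given "over the list alone" count the genes that passed when adjusted over that list instead of all genes. The 95% intervals of log2 changes come from these errors and so include the spread between libraries.

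Several genes were followed through the comparisons, with positions from GENCODE on GRCh38. POU5F1 (ENSG00000204531, chromosome 6, 31164337 to 31180731) encodes OCT4, which maintains pluripotency. STMN2 (ENSG00000104435, chromosome 8, 79610814 to 79666175) encodes a microtubule regulator of growing axons, and NEUROD1 (ENSG00000162992, chromosome 2, 181673088 to 181680876) a transcription factor of newly formed neurons. HES5 (ENSG00000197921, chromosome 1, 2528745 to 2530245) and HES1 (ENSG00000114315, chromosome 3, 194136145 to 194138732) are switched on by Notch. PROX1 (ENSG00000117707, chromosome 1, 213983181 to 214041502) and CALB1 (ENSG00000104327, chromosome 8, 90058608 to 90095475) mark dentate granule neurons.

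**Figure D1:**
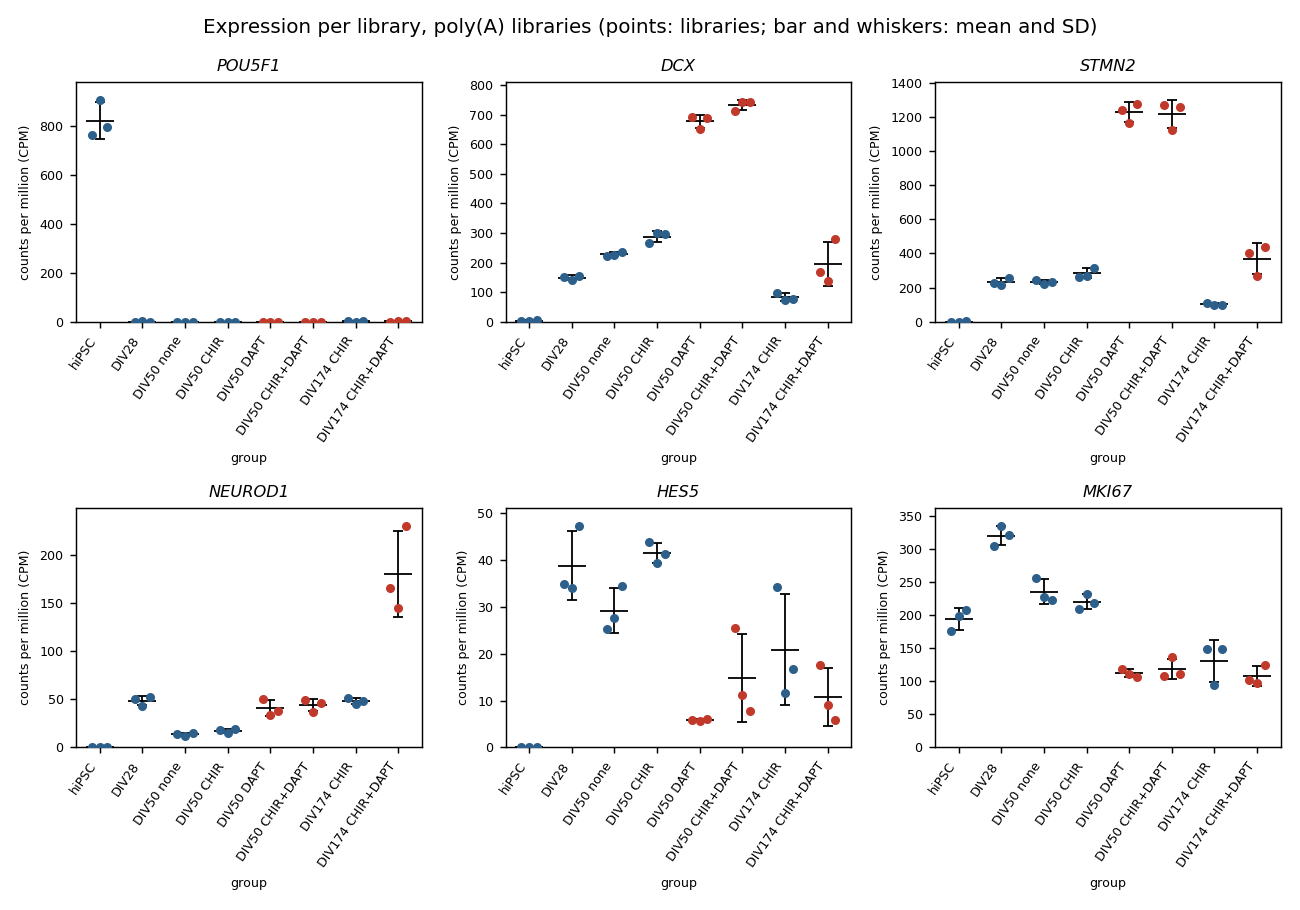
CPM of 6 genes in each of the 24 poly(A) libraries, by group (points, libraries; bar and whiskers, mean and SD; red, groups with DAPT; blue, groups without). POU5F1 averaged 823 CPM in hiPSC and 0.587 CPM at DIV28, DCX averaged 149 CPM at DIV28, and STMN2 was highest in the DIV50 groups with DAPT (1230 and 1220 CPM).

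DIV28 against hiPSC joins neural induction and, by the protocol, CHIR from DIV16, not separable here. Pluripotency genes fell and genes of dorsal forebrain progenitors and young neurons rose. POU5F1 fell from 823 ± 75.6 to 0.587 ± 0.321 CPM (log2 change -10.58 ± 0.38, adjusted p = 6.8e-16), and L1TD1, an RNA-binding protein of pluripotent cells, fell from 502 ± 37.8 to 0.269 ± 0.0861 CPM. LHX2 and PAX6, transcription factors of the forebrain neuroepithelium, rose from 0.991 ± 1.12 to 161 ± 17.9 CPM and from 3.43 ± 3.72 to 458 ± 31.7 CPM. STMN2 rose from 0.468 ± 0.505 to 234 ± 21.2 CPM (log2 change 8.75 ± 0.30, adjusted p = 4.1e-17). In all, 9645 genes changed, 4713 higher and 4932 lower.

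Of 21 pluripotency genes measured, 0 rose, 19 fell and 2 did not pass (0 and 19 over the list alone, camera adjusted p = 4.3e-20), among them the de novo DNA methyltransferase DNMT3B (from 879 ± 71.5 to 46.9 ± 3.41 CPM). Among dorsal telencephalon genes 15 of 15 rose (15 over the list alone, camera adjusted p = 1.6e-43). OTX1 went from 4.19 ± 1.1 to 171 ± 6.55 CPM. Radial glia are the stem cells of the developing brain, and of their genes 16 of 21 rose (16 over the list alone, camera adjusted p = 1.8e-17). VIM rose from 53.5 ± 2.2 to 1230 ± 72 CPM and FABP7 from 5.06 ± 1.16 to 234 ± 32.5 CPM, whereas SOX2 did not differ (141 ± 19.1 against 144 ± 5.34 CPM, adjusted p = 0.9). Of the proneural and intermediate progenitor genes, which commit progenitors to neurogenesis, 19 of 21 rose (19 over the list alone, camera adjusted p = 4.8e-33). NEUROG2 stood at 154 ± 13.6 CPM against 0.0451 ± 0.0502 in hiPSC, and NEUROD1 at 48.7 ± 4.91 against 0.024 ± 0.0416. In the immature neuron list 22 rose, 2 fell and 0 did not pass (22 and 2 over the list alone, camera adjusted p = 4e-45). DCX, a microtubule protein of migrating neurons, went from 2.84 ± 1.38 to 149 ± 7.5 CPM and TUBB3 from 45.9 ± 9.71 to 740 ± 59.4 CPM. Of the genes for Notch ligands and genes that Notch represses, 8 rose, 2 fell and 0 did not pass (8 and 2 over the list alone, camera adjusted p = 8.3e-13). The ligand DLL1 rose from 10.1 ± 0.998 to 186 ± 11 CPM. Among Wnt targets 11 rose, 3 fell and 4 did not pass (11 and 3 over the list alone, camera adjusted p = 0.00023). The transcription factor LEF1 went from 6.82 ± 1.42 to 360 ± 20.6 CPM. In the dentate granule lineage list 11 rose, 4 fell and 5 did not pass (11 and 4 over the list alone, camera adjusted p = 0.00021). PROX1 reached 4.99 ± 0.558 CPM (log2 change 3.11 ± 0.49, adjusted p = 6.3e-06).

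Genes of adhesion and of tension-dependent transcription fell at DIV28. Of 20 targets of YAP and SRF, 3 rose, 16 fell and 1 did not pass (3 and 16 over the list alone, camera adjusted p = 6.1e-06). Tropomyosin TPM1 went from 794 ± 64.4 to 53.9 ± 5.54 CPM. For integrins and focal adhesions 2 rose, 13 fell and 4 did not pass (2 and 13 over the list alone, camera adjusted p = 0.00063), vinculin (VCL) among them (from 512 ± 86.6 to 70.8 ± 7.74 CPM). Hypoxia and glycolysis genes also moved down, as 2 rose, 12 fell and 2 did not pass (2 and 12 over the list alone, camera adjusted p = 0.00034, adjusted p = 0.24 with an estimated correlation). LDHA went from 795 ± 116 to 62.7 ± 2.4 CPM. Notch targets mostly rose: 8 rose, 1 fell and 3 did not pass (8 and 1 over the list alone, camera adjusted p = 0.0016, adjusted p = 0.13 with an estimated correlation). HES1 went from 35.8 ± 8.65 to 80.1 ± 15.5 CPM. Cell cycle genes went both ways, with 16 of the 43 S-phase genes rising and 9 falling (16 and 10 over the list alone, camera adjusted p = 0.34), and 9 of the 52 G2/M genes rising and 25 falling (10 and 25 over the list alone, camera adjusted p = 0.17). MKI67, a marker of cycling cells, rose from 194 ± 16.1 to 320 ± 14.8 CPM (adjusted p = 4.1e-05, and up to 0.12 over the alternatives, with transcript length offsets). Gene list calls named without a second p held with an estimated correlation. That second p can be far larger, as 0.003 against 1.2e-56 for G2/M genes with DAPT alone at DIV50. Over all 17 comparisons and 37 lists, 241 of 629 camera tests passed and 109 of them held with an estimated correlation.

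DIV50 without factors against DIV28 follows the cultures into differentiation medium. Genes of the dorsal telencephalon fell, while genes of the midbrain and hindbrain and of hypoxia rose. LHX2 fell from 161 ± 17.9 to 11.7 ± 2.3 CPM (log2 change -3.79 ± 0.29, adjusted p = 7.6e-10) and TBR1, a transcription factor of excitatory cortical neurons, from 94.4 ± 1.46 to 10.8 ± 3.44 CPM. PCDH8, a cell adhesion protein, rose from 2.31 ± 1.37 to 324 ± 31.4 CPM and TH, which makes the catecholamine precursor L-DOPA, from 0.964 ± 0.164 to 104 ± 5.23 CPM. In all, 6807 genes changed, 3654 higher and 3153 lower.

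Of 15 dorsal telencephalon genes, 1 rose, 13 fell and 1 did not pass (1 and 13 over the list alone, camera adjusted p = 2e-19). EMX2 went from 117 ± 13.1 to 17.4 ± 1.86 CPM. Among midbrain and hindbrain genes 7 of 11 rose (8 over the list alone, camera adjusted p = 4.8e-09). IRX3 went from 1.25 ± 0.13 to 56.9 ± 9.9 CPM and PAX3, a gene of the dorsal neural tube, from 0.277 ± 0.386 to 163 ± 22 CPM. In the hypoxia and glycolysis list 14 of 16 rose (14 over the list alone, camera adjusted p = 2.2e-29). PGK1 went from 311 ± 11 to 1980 ± 346 CPM and BNIP3, a mitophagy receptor, from 64.9 ± 8.62 to 749 ± 146 CPM. Targets of p53 went down, as 1 rose, 14 fell and 1 did not pass (1 and 14 over the list alone, camera adjusted p = 2.5e-12). The nuclease gene AEN fell from 224 ± 17.1 to 48.5 ± 4.92 CPM. Retinoic acid response genes moved up, as 7 rose, 1 fell and 5 did not pass (7 and 1 over the list alone, camera adjusted p = 0.00018). CRABP1, which binds retinoic acid in the cytoplasm, went from 35.5 ± 2.35 to 1130 ± 33 CPM. Of 18 neural crest and mesenchyme genes, 7 rose, 3 fell and 8 did not pass (7 and 3 over the list alone, camera adjusted p = 0.0063), among them TFAP2B (from 0.159 ± 0.153 to 30.8 ± 5.32 CPM).

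Neuronal lists split. In the immature neuron list 10 of 24 rose (10 over the list alone, camera adjusted p = 0.0049, adjusted p = 0.27 with an estimated correlation). The neurofilament genes NEFL (from 95.1 ± 14.1 to 492 ± 39.2 CPM) and NEFM (from 83.9 ± 4.9 to 443 ± 37.6 CPM) were among them, while STMN2 did not differ (adjusted p = 0.98). Proneural and intermediate progenitor genes moved down, as 2 rose, 9 fell and 10 did not pass (2 and 9 over the list alone, camera adjusted p = 0.0043, adjusted p = 0.2 with an estimated correlation). NEUROG2 went from 154 ± 13.6 to 18.6 ± 4.56 CPM and EOMES, a marker of intermediate progenitors, from 49.5 ± 6 to 5.15 ± 1.78 CPM. Of 21 radial glia genes, 2 rose, 8 fell and 11 did not pass (2 and 8 over the list alone, camera adjusted p = 0.019, adjusted p = 0.16 with an estimated correlation). PROX1 rose from 4.99 ± 0.558 to 12.9 ± 4.08 CPM (adjusted p = 0.0076). MKI67 fell from 320 ± 14.8 to 235 ± 18.3 CPM (adjusted p = 0.0085, and up to 0.45 over the alternatives, with transcript length offsets). Of the G2/M genes 9 rose, 11 fell and 32 did not pass (9 and 11 over the list alone, camera adjusted p = 0.89). That balance turned to 11 rising and 10 falling with DESeq2 size factors in edgeR or a stricter filter, and to 13 and 10 with no filter on low counts. Mitochondrially encoded mRNAs were lower, as 12 of 13 fell (13 over the list alone, camera adjusted p = 1e-06, adjusted p = 0.2 with an estimated correlation). Day, run and any end of CHIR medium cannot be separated here, and the labels name no run.

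DIV50 CHIR against no factor asks what continued GSK3 inhibition did on its own. edgeR called 11 genes, 10 higher and 1 lower, and 1103 genes had an unadjusted p under 0.05. No Wnt target gene was among the 11 called. Mitochondrially encoded transcripts made up part of the rise. MT-CYB went from 1290 ± 198 to 2470 ± 39.1 CPM (log2 change 0.94 ± 0.15, adjusted p = 0.02) and MT-CO3 from 1920 ± 312 to 3670 ± 160 CPM. TFAP2B rose from 30.8 ± 5.32 to 62.3 ± 0.989 CPM (log2 change 1.02 ± 0.18, adjusted p = 0.025). CTNNA2, which links cadherins to actin in neurons, fell from 205 ± 30.4 to 133 ± 5.84 CPM.

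Of 13 mitochondrially encoded mRNAs, 4 rose, 0 fell and 9 did not pass (13 and 0 over the list alone, camera adjusted p = 1.3e-38). No Wnt target passed, as 0 rose, 0 fell and 18 did not pass (0 and 0 over the list alone, camera adjusted p = 0.91). AXIN2, a feedback inhibitor switched on by β-catenin, stood at 46.4 ± 4.97 against 44 ± 7.18 CPM (log2 change 0.08 ± 0.18, 95% interval -0.31 to 0.46). LEF1 stood at 69.5 ± 6.78 against 63.4 ± 1.98 CPM (adjusted p = 0.93) and SP5 at 15.9 ± 1.73 against 8.14 ± 0.813 CPM (log2 change 0.97 ± 0.33, adjusted p = 0.57). Before adjustment, 2 of the 18 had 95% intervals above 0, SP5 (0.27 to 1.66) and NKD1 (0.16 to 1.33, 18.2 ± 1.26 against 10.9 ± 0.412 CPM, adjusted p = 0.64). With only these groups in the fit both passed (adjusted p = 0.012 and 0.032), while with length offsets the log2 change of NKD1 was -0.38. Cytosolic ribosomal protein genes shifted up together though none passed alone, as 0 of 31 rose (16 over the list alone, camera adjusted p = 6.9e-26, adjusted p = 0.13 with an estimated correlation). The immature neuron list shifted up (camera adjusted p = 1.6e-08, adjusted p = 0.092 with an estimated correlation), with 0 of 24 genes passing (2 rising over the list alone). Other lists shifted down with no gene passing. Their camera adjusted p, and that with an estimated correlation, were 8.2e-09 and 0.13 for S phase, and 2.1e-07 and 0.32 for G2/M. They were 4.2e-08 and 0.13 for cholesterol synthesis, and 0.00014 and 0.061 for YAP and SRF targets. In all, 8 of 37 lists passed upward and 7 downward, and 1, the mitochondrially encoded mRNAs, held with an estimated correlation. STMN2 did not differ (283 ± 29.2 against 232 ± 10.1 CPM, adjusted p = 0.86). Neither HES5 (adjusted p = 0.9), PROX1 (adjusted p = 1) nor MKI67 (adjusted p = 0.96) passed. The count rested on every library, since leaving out any 1 of the 6 left 0 or 1 gene. MT-CYB still passed without replicate 3 of the no-factor group, and the other genes named as changed passed in no such fit (adjusted p up to 0.45 for CTNNA2). DESeq2 called 51, no filter on low counts gave 220, only the groups compared in the fit 216, and transcript length offsets 3. The share of called genes that were higher was 90.9%, 76.5% with DESeq2 and 66.7% with length offsets.

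DIV50 DAPT against no factor asks what blocking Notch did without CHIR. Neuronal genes rose and cell cycle and stem cell genes fell. STMN2 rose from 232 ± 10.1 to 1230 ± 57.8 CPM (log2 change 2.40 ± 0.19, adjusted p = 5e-09), NEFM from 443 ± 37.6 to 2820 ± 131 CPM and DCX from 229 ± 7.35 to 678 ± 21.4 CPM. HES5 fell from 29.2 ± 4.81 to 5.89 ± 0.189 CPM (log2 change -2.30 ± 0.42, adjusted p = 0.0003) and HES1 from 71.2 ± 2.4 to 47.6 ± 8.77 CPM (adjusted p = 0.017, and up to 0.082 without replicate 1 or 3 of the DAPT group). In all, 3881 genes changed, 2072 higher and 1809 lower.

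Every immature neuron gene passed, as 24 of 24 rose (24 over the list alone, camera adjusted p = 5.8e-70). GAP43, a growth cone protein, went from 181 ± 24.6 to 940 ± 119 CPM. Of 21 proneural and intermediate progenitor genes, 15 rose, 1 fell and 5 did not pass (16 and 1 over the list alone, camera adjusted p = 4e-14). NEUROD1 went from 13.7 ± 1.55 to 40.6 ± 8.31 CPM, EOMES from 5.15 ± 1.78 to 19.5 ± 4.86 CPM and INSM1 from 26 ± 1.18 to 119 ± 17 CPM. In the synapse and excitability list 13 of 24 rose (14 over the list alone, camera adjusted p = 3.8e-11). The vesicle calcium sensor SYT1 went from 105 ± 11.9 to 351 ± 30.9 CPM. Transmitter identity genes rose in several classes: among GABAergic neuron genes 10 of 13 rose (10 over the list alone, camera adjusted p = 5.8e-08). GAD2 stood at 8.04 ± 0.917 against 1.72 ± 0.494 CPM, and among glutamatergic neuron genes 5 of 12 rose (6 over the list alone, camera adjusted p = 8.2e-06). Of 13 Cajal-Retzius genes, which mark an early neuron of the hem and cortex surface, 10 rose, 1 fell and 2 did not pass (11 and 1 over the list alone, camera adjusted p = 2.7e-09), among them EBF2 (from 29.3 ± 1.91 to 157 ± 17.1 CPM). Of 20 dentate granule lineage genes, 6 rose, 1 fell and 13 did not pass (6 and 1 over the list alone, camera adjusted p = 0.0074). PROX1 itself did not pass (21.4 ± 3.22 against 12.9 ± 4.08 CPM, adjusted p = 0.17, from 0.024 with only these groups in the fit to 0.48 over the alternatives). The largest rises included TFAP2A (from 3.1 ± 0.956 to 23.3 ± 4.12 CPM), the neuropeptide gene SST (from 5.73 ± 1.08 to 39.7 ± 2.66 CPM) and POU4F1, a transcription factor of sensory neurons (from 21.1 ± 3.65 to 145 ± 28.1 CPM).

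Of the G2/M genes 47 of 52 fell (48 over the list alone, camera adjusted p = 1.2e-56) and of the S-phase genes 32 of 43 fell (37 over the list alone, camera adjusted p = 5.4e-17). MKI67 went from 235 ± 18.3 to 112 ± 5.88 CPM (adjusted p = 9.8e-07) and TOP2A from 745 ± 45.5 to 272 ± 25.5 CPM. Among radial glia genes 15 of 21 fell (17 over the list alone, camera adjusted p = 2.9e-11). SOX2 went from 149 ± 17.2 to 77.3 ± 11.7 CPM, VIM from 3190 ± 237 to 1470 ± 130 CPM and SOX9 from 45.4 ± 3.8 to 15.8 ± 0.513 CPM. Of 12 Notch targets, 1 rose, 6 fell and 5 did not pass (1 and 6 over the list alone, camera adjusted p = 0.001, adjusted p = 0.1 with an estimated correlation). NOTCH3 went from 166 ± 22.8 to 77.6 ± 17 CPM and DTX4 from 206 ± 26.5 to 104 ± 12.8 CPM. Genes for Notch ligands and genes that Notch represses moved the other way, as 7 rose, 1 fell and 2 did not pass (7 and 1 over the list alone, camera adjusted p = 0.00016). DLL3 rose from 102 ± 3.98 to 250 ± 24.9 CPM and DLL1 fell from 196 ± 22.9 to 106 ± 9.43 CPM. In the laminin and basement membrane list 11 of 18 fell (11 over the list alone, camera adjusted p = 8.7e-07). Wnt targets showed no shift as a list, as 1 rose, 4 fell and 13 did not pass (2 and 4 over the list alone, camera adjusted p = 0.18). LEF1 fell from 63.4 ± 1.98 to 45.6 ± 6.25 CPM (adjusted p = 0.0049). AXIN2 fell from 44 ± 7.18 to 30.6 ± 2.78 CPM (adjusted p = 0.042), a call lost without any 1 library except replicate 1 of the no-factor group and with length offsets (adjusted p up to 0.16).

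DIV50 CHIR+DAPT against CHIR asks the question of Notch blockade with CHIR present. Neuronal genes rose and dividing-cell genes fell here as well. STMN2 rose from 283 ± 29.2 to 1220 ± 81.9 CPM (log2 change 2.10 ± 0.19, adjusted p = 2.8e-08), and ROBO3, a guidance receptor of commissural axons, rose from 113 ± 11.1 to 647 ± 51.8 CPM. ID1, an inhibitor of proneural factors, fell from 77.8 ± 5.46 to 19.5 ± 2.93 CPM (adjusted p = 7.4e-10), and the neurotrophin receptor NTRK2 from 153 ± 4.93 to 39.3 ± 9.13 CPM. In all, 4005 genes changed, 2143 higher and 1862 lower.

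Of the immature neuron genes 24 of 24 rose (24 over the list alone, camera adjusted p = 3.5e-57). NEFM went from 571 ± 40 to 2630 ± 260 CPM and DCX from 288 ± 18.4 to 733 ± 16.7 CPM. Of 21 proneural and intermediate progenitor genes, 16 rose, 1 fell and 4 did not pass (17 and 1 over the list alone, camera adjusted p = 2.3e-18). NEUROD1 went from 17.5 ± 2.13 to 44.1 ± 6.31 CPM, EOMES from 5.97 ± 1.98 to 22.5 ± 2.12 CPM and NHLH1 from 77.9 ± 14.3 to 326 ± 8.49 CPM. In the synapse and excitability list 12 of 24 rose (13 over the list alone, camera adjusted p = 1.1e-10), and in the glutamatergic neuron list 5 of 12 rose (7 over the list alone, camera adjusted p = 9.7e-05). Of 13 Cajal-Retzius genes, 10 rose, 1 fell and 2 did not pass (11 and 1 over the list alone, camera adjusted p = 1.6e-08). Of 13 GABAergic neuron genes 9 rose, 1 fell and 3 did not pass (9 and 1 over the list alone, camera adjusted p = 1.2e-05). In the dentate granule lineage list 5 of 20 rose (6 over the list alone, camera adjusted p = 0.0079). PROX1 did not pass (22.6 ± 3.95 against 13.1 ± 3.71 CPM, adjusted p = 0.14, from 0.011 with only these groups in the fit to 0.42 over the alternatives).

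G2/M genes went down, as 47 of 52 fell (49 over the list alone, camera adjusted p = 3.5e-59), and S-phase genes too, as 33 of 43 fell (36 over the list alone, camera adjusted p = 6.9e-17). MKI67 went from 220 ± 11.4 to 119 ± 15.6 CPM. Of 21 radial glia genes, 1 rose, 14 fell and 6 did not pass (1 and 16 over the list alone, camera adjusted p = 4.1e-09). SOX2 went from 173 ± 17.2 to 95.6 ± 19.9 CPM and VIM from 3280 ± 17.8 to 1500 ± 60 CPM. Among Notch targets 6 of 12 fell (7 over the list alone, camera adjusted p = 0.011, adjusted p = 0.24 with an estimated correlation). HES5 went from 41.5 ± 2.19 to 14.9 ± 9.41 CPM (adjusted p = 0.0081, and 0.051 without replicate 2 of CHIR+DAPT) and HES1 from 69.5 ± 5.3 to 35.6 ± 6.94 CPM (adjusted p = 0.00021). Genes for Notch ligands and genes that Notch represses moved up, as 6 rose, 1 fell and 3 did not pass (8 and 1 over the list alone, camera adjusted p = 4.8e-07), led by DLL3 (from 121 ± 2.17 to 326 ± 11.4 CPM). The replication-dependent histones were lower, as 6 of 14 fell (6 over the list alone, camera adjusted p = 0.0024). How fully the poly(A) kit captured histone transcripts was not tested, here or in the other poly(A) comparisons. Neither AXIN2 (adjusted p = 0.66) nor LEF1 (adjusted p = 0.98) passed.

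**Figure D2:**
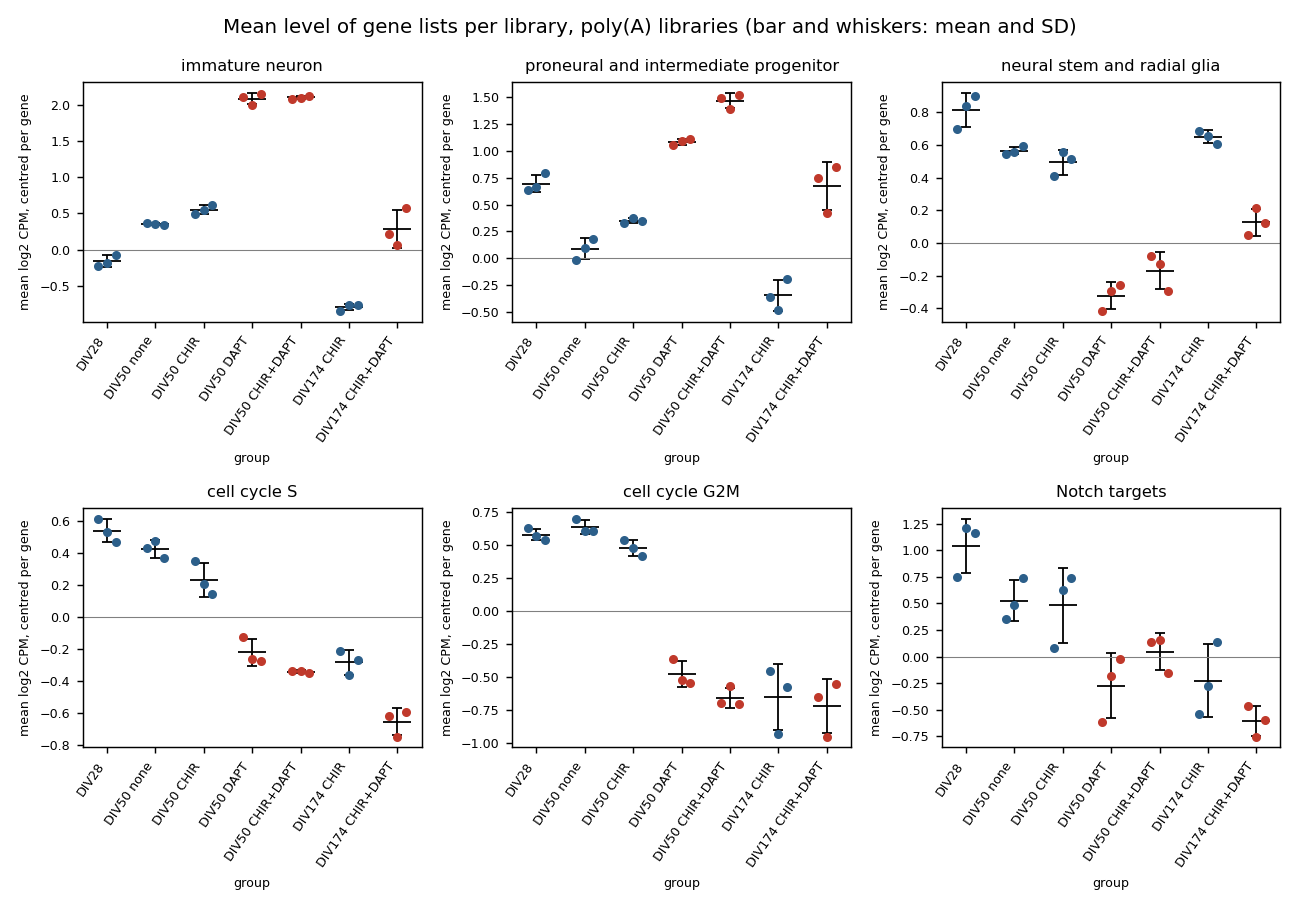
Mean log2 CPM of 6 gene lists in each poly(A) library after hiPSC, centred per gene over all poly(A) libraries, hiPSC included, by group (points, libraries; bar and whiskers, mean and SD; red, groups with DAPT; blue, groups without). All 24 immature neuron genes rose with DAPT at DIV50 in CHIR, and 47 of 52 G2/M genes fell.

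DIV50 CHIR+DAPT against no factor measures both factors together. It called 4461 genes, 2319 higher and 2142 lower, with neuronal genes up and proliferation genes down. ROBO3 rose from 71.5 ± 3.35 to 647 ± 51.8 CPM (log2 change 3.18 ± 0.21, adjusted p = 2.7e-10), TLX3, a transcription factor of dorsal sensory neurons, rose from 8.94 ± 3.59 to 74.6 ± 3.93 CPM, and TFAP2B from 30.8 ± 5.32 to 255 ± 19.2 CPM. ID1 fell from 93.3 ± 7.92 to 19.5 ± 2.93 CPM. Of the immature neuron genes 23 of 24 rose (23 over the list alone, camera adjusted p = 1.3e-62). STMN2 stood at 1220 ± 81.9 against 232 ± 10.1 CPM. Of the G2/M genes 49 of 52 fell (50 over the list alone, camera adjusted p = 1.9e-64) and of the S-phase genes 38 of 43 fell (41 over the list alone, camera adjusted p = 8.1e-24). Of 21 proneural and intermediate progenitor genes, 17 rose, 1 fell and 3 did not pass (18 and 1 over the list alone, camera adjusted p = 2.2e-23). NEUROD1 went from 13.7 ± 1.55 to 44.1 ± 6.31 CPM. HES1 fell from 71.2 ± 2.4 to 35.6 ± 6.94 CPM (adjusted p = 0.00011), whereas HES5 did not pass (14.9 ± 9.41 against 29.2 ± 4.81 CPM, adjusted p = 0.072, from 4.3e-05 with no filter on low counts to 0.27 over the alternatives, and 0.0028 without replicate 1 of CHIR+DAPT). The Wnt feedback gene NKD1 rose from 10.9 ± 0.412 to 24.4 ± 2.76 CPM (adjusted p = 0.0023, and up to 0.37 over the alternatives, with length offsets), while LEF1 did not pass (adjusted p = 0.43). Genes of the basement membrane moved down, as in the laminin and basement membrane list 2 rose, 12 fell and 4 did not pass (3 and 13 over the list alone, camera adjusted p = 7e-07). SPARC went from 921 ± 103 to 274 ± 11 CPM.

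DIV50 CHIR+DAPT against DAPT isolates CHIR under Notch blockade. A small set changed, 83 genes, 44 higher and 39 lower. Of 18 Wnt targets 1 rose, 1 fell and 16 did not pass (2 and 2 over the list alone, camera adjusted p = 0.071). The Wnt effector LEF1 was higher with CHIR (69.9 ± 6.03 against 45.6 ± 6.25 CPM, log2 change 0.61 ± 0.12, adjusted p = 0.014, and up to 0.13 without replicate 2 or 3 of either group). BAMBI, another Wnt target, was lower (5.72 ± 1.26 against 12.7 ± 2.12 CPM, adjusted p = 0.015, and up to 0.14 without replicate 1 or 2 of either group), and AXIN2 did not pass (42.3 ± 4.79 against 30.6 ± 2.78 CPM, adjusted p = 0.38). TFAP2B rose from 88.2 ± 3.21 to 255 ± 19.2 CPM (log2 change 1.53 ± 0.18, adjusted p = 0.0001) and MYBPC1, a myosin-binding protein, from 10.5 ± 2.78 to 45.7 ± 5.22 CPM. RGS16, a regulator of G protein signals, rose from 86 ± 5.78 to 213 ± 41 CPM. The keratin gene KRT18 fell from 18 ± 3.63 to 6.68 ± 0.994 CPM. Among proneural and intermediate progenitor genes 3 of 21 rose (5 over the list alone, camera adjusted p = 1.8e-11). NHLH1 went from 180 ± 30.9 to 326 ± 8.49 CPM. Targets of YAP and SRF moved down, as 4 of 20 fell (7 over the list alone, camera adjusted p = 1.7e-09). AJUBA went from 54.6 ± 5.83 to 33.6 ± 4.85 CPM (adjusted p up to 0.092 over the alternatives, without replicate 2 of the DAPT group or with length offsets). Hypoxia and glycolysis genes moved down, as 2 of 16 fell (13 over the list alone, camera adjusted p = 2.2e-17), and so did cholesterol synthesis genes, as 3 of 20 fell (11 over the list alone, camera adjusted p = 9.1e-16). IDI1 went from 685 ± 18.9 to 442 ± 7.9 CPM. Neither STMN2 (adjusted p = 1) nor MKI67 (adjusted p = 0.92) passed. Every library mattered to the count, since leaving out 1 of the 6 gave 21 to 47 genes, and DESeq2 called 218, no filter on low counts gave 397, only the groups compared in the fit 304, and length offsets 35.

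The interaction of CHIR and DAPT at DIV50 tests whether the factors depended on one another. edgeR called 0 genes, 880 had an unadjusted p under 0.05, and DESeq2 called 10 (50% of them higher). In a simulation of this interaction edgeR recovered 1.5% of genes planted at 1.5-fold, 31.3% at 2-fold and 66.7% at 4-fold, so a count of 0 does not exclude such differences. Leaving out replicate 2 of the CHIR group or replicate 1 of the DAPT group each gave 1 gene, and no filter on low counts gave 84. Neither STMN2 (difference of log2 changes -0.30 ± 0.25, adjusted p = 1), HES5 (0.82 ± 0.56, adjusted p = 1), LEF1 (0.48 ± 0.17, adjusted p = 0.92) nor MKI67 (adjusted p = 1) passed. Replication-dependent histones shifted down as a list (camera adjusted p = 6.4e-05, and 0.0066 with an estimated correlation), with 0 of 14 passing on their own (0 over the list alone). That estimated correlation was -0.034, below the preset of 0.01, so it made no allowance for genes moving together. The median log2 change of this list was 0.409 with CHIR alone and -0.32 with CHIR under DAPT. Thus for STMN2 the rise with DAPT alone was not shown to differ from the rise in CHIR.

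DIV174 CHIR+DAPT against CHIR asks whether Notch blockade still acted in old cultures. Neuronal and proneural genes were higher with DAPT, S-phase and laminin and basement membrane genes were lower, and no G2/M gene passed. NEUROD1 stood at 180 ± 44.6 against 48.3 ± 2.7 CPM (log2 change 1.90 ± 0.17, adjusted p = 3.6e-08) and STMN2 at 368 ± 90.9 against 102 ± 8.57 CPM (log2 change 1.85 ± 0.19, adjusted p = 1e-06). SYT4, a synaptotagmin of dense-core vesicles, stood at 230 ± 49.7 against 53.8 ± 4.81 CPM. In all, 877 genes changed, 546 higher and 331 lower. Without replicate 1 or replicate 3 of the CHIR group the count was 574 or 582, and with only these groups in the fit it was 227.

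Of the immature neuron genes 18 of 24 rose (21 over the list alone, camera adjusted p = 9.7e-68). DCX stood at 194 ± 74.5 against 82.5 ± 13 CPM. Among proneural and intermediate progenitor genes 15 of 21 rose (17 over the list alone, camera adjusted p = 2.3e-42). EOMES stood at 111 ± 29.7 against 34.9 ± 10.6 CPM, NHLH1 at 313 ± 45.2 against 83.1 ± 0.875 CPM and NEUROD4 at 28.1 ± 0.901 against 6.72 ± 3.05 CPM. Of the genes for Notch ligands and genes that Notch represses, 5 of 10 rose (7 over the list alone, camera adjusted p = 1.7e-14). DLL3 stood at 234 ± 39.6 against 73.7 ± 1.53 CPM and DLL1 at 146 ± 32.6 against 101 ± 11.3 CPM (adjusted p up to 0.14 without replicate 1 or 2 of CHIR or replicate 3 of CHIR+DAPT). In the synapse and excitability list 6 of 24 rose (7 over the list alone, camera adjusted p = 2e-07). In the Cajal-Retzius list 6 of 13 rose (9 over the list alone, camera adjusted p = 5.8e-12), and in the dentate granule lineage list 2 of 20 rose (3 over the list alone, camera adjusted p = 0.02). Those 2 dentate genes were NEUROD1, also on the proneural list, and DCX, also on the immature neuron list. TBR1 was higher (87.1 ± 31.7 against 27.9 ± 1.2 CPM), and PROX1 did not pass (13.7 ± 6.06 against 9.49 ± 1.27 CPM, adjusted p = 0.53).

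Among S-phase genes 14 of 43 fell (23 over the list alone, camera adjusted p = 4.3e-14). The replication helicase subunit MCM4 stood at 107 ± 14.1 against 179 ± 14.5 CPM. Among G2/M genes 0 of 52 fell (0 over the list alone, camera adjusted p = 0.31). MKI67 did not pass (108 ± 15.2 against 130 ± 31.6 CPM, adjusted p = 0.29, and 0.023 without replicate 2 of the CHIR group). Radial glia genes moved down, as 5 of 21 fell (7 over the list alone, camera adjusted p = 1.2e-07). Notch targets did so too, as 2 of 12 fell (3 over the list alone, camera adjusted p = 0.00096, adjusted p = 0.084 with an estimated correlation). However, HES1 (118 ± 22.6 against 154 ± 21.4 CPM, adjusted p = 0.26) and HES5 (10.8 ± 6.14 against 20.9 ± 11.9 CPM, adjusted p = 0.21, from 0.0011 with no filter on low counts to 0.71 over the alternatives) did not pass. In the laminin and basement membrane list 1 rose, 6 fell and 11 did not pass (2 and 10 over the list alone, camera adjusted p = 4.2e-07). LAMA1 stood at 32.7 ± 4.82 against 67.1 ± 16.4 CPM. Targets of YAP and SRF were lower, as 6 of 20 fell (6 over the list alone, camera adjusted p = 0.00068). Cholesterol synthesis genes were higher, as 6 rose, 0 fell and 14 did not pass (10 and 1 over the list alone, camera adjusted p = 3.4e-08, adjusted p = 0.084 with an estimated correlation). INSIG1 stood at 112 ± 6.33 against 67.2 ± 14.4 CPM. Leaving out replicate 1 of CHIR+DAPT, a choice made after its values were seen, gave 17 immature neuron, 15 proneural and 12 S-phase genes and 4 Notch targets.

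DIV174 CHIR against DIV50 CHIR follows the cultures over time with CHIR. Genes of the midbrain and hindbrain, of G2/M and of young neurons fell, and genes of stress and hypoxia rose. TH fell from 215 ± 21.3 to 0.591 ± 0.325 CPM (log2 change -8.43 ± 0.48, adjusted p = 1.3e-10), EBF1 from 217 ± 25 to 2.23 ± 0.247 CPM and ID3 from 254 ± 17.6 to 4.06 ± 0.456 CPM. CA9, a carbonic anhydrase induced by low oxygen, rose from 0.618 ± 0.0147 to 109 ± 26.7 CPM (log2 change 7.45 ± 0.37, adjusted p = 3.9e-14), and OLIG1, a transcription factor of oligodendrocyte progenitors, from 5.04 ± 0.698 to 198 ± 61.8 CPM. In all, 6916 genes changed, 3119 higher and 3797 lower.

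Among midbrain and hindbrain genes 9 of 11 fell (9 over the list alone, camera adjusted p = 8.4e-11). Of 15 cortical hem genes 2 rose, 12 fell and 1 did not pass (2 and 12 over the list alone, camera adjusted p = 6e-10). Of 15 dorsal telencephalon genes, 9 rose, 2 fell and 4 did not pass (9 and 2 over the list alone, camera adjusted p = 2.8e-06). LHX2 went from 9.4 ± 1.19 to 69.5 ± 7.93 CPM and SP8 from 8.41 ± 1.7 to 61.9 ± 5.56 CPM. Proneural genes went both ways, as 4 rose, 10 fell and 7 did not pass (4 and 10 over the list alone, camera adjusted p = 0.002, adjusted p = 0.22 with an estimated correlation). NEUROD1 rose from 17.5 ± 2.13 to 48.3 ± 2.7 CPM and EOMES from 5.97 ± 1.98 to 34.9 ± 10.6 CPM. Among immature neuron genes 19 of 24 fell (20 over the list alone, camera adjusted p = 3e-14). STMN2 went from 283 ± 29.2 to 102 ± 8.57 CPM and NEFM from 571 ± 40 to 115 ± 17.5 CPM. Of the G2/M genes 49 of 52 fell (50 over the list alone, camera adjusted p = 6.9e-24) and of the S-phase genes 25 of 43 fell (26 over the list alone, camera adjusted p = 3.2e-05, adjusted p = 0.23 with an estimated correlation). MKI67 went from 220 ± 11.4 to 130 ± 31.6 CPM. AXIN2 fell from 46.4 ± 4.97 to 8.09 ± 2.14 CPM (log2 change -2.51 ± 0.20, adjusted p = 1.3e-10). In the hypoxia and glycolysis list 15 rose, 0 fell and 1 did not pass (15 and 1 over the list alone, camera adjusted p = 3e-14). PGK1 went from 1860 ± 125 to 4930 ± 613 CPM, and in the stress and unfolded protein list 14 rose, 1 fell and 1 did not pass (14 and 1 over the list alone, camera adjusted p = 2.8e-13). ASNS, an asparagine synthetase, went from 106 ± 11.7 to 455 ± 58.3 CPM. Of the mitochondrially encoded mRNAs 13 of 13 fell (13 over the list alone, camera adjusted p = 3e-14, adjusted p = 0.053 with an estimated correlation). CRABP1 fell from 1460 ± 94.8 to 29.3 ± 10.4 CPM. HES1 rose from 69.5 ± 5.3 to 154 ± 21.4 CPM.

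DIV174 CHIR+DAPT against DIV50 CHIR+DAPT makes the same comparison of days under Notch blockade. Again 6535 genes changed, 2853 higher and 3682 lower, and young-neuron genes fell. STMN2 fell from 1220 ± 81.9 to 368 ± 90.9 CPM (log2 change -1.72 ± 0.18, adjusted p = 9.7e-08), TH from 657 ± 89.2 to 1.53 ± 1.38 CPM and CRABP1 from 3080 ± 334 to 42 ± 12.4 CPM. SYTL2, a vesicle trafficking protein, rose from 2.79 ± 0.611 to 167 ± 29.2 CPM (log2 change 5.91 ± 0.22, adjusted p = 1.1e-16), and LOX, which crosslinks collagen, from 10.9 ± 2.83 to 268 ± 69.8 CPM. Among immature neuron genes 23 of 24 fell (23 over the list alone, camera adjusted p = 3.3e-26). Of 21 proneural genes 2 rose, 13 fell and 6 did not pass (2 and 13 over the list alone, camera adjusted p = 0.0014, adjusted p = 0.16 with an estimated correlation). NEUROD1 rose from 44.1 ± 6.31 to 180 ± 44.6 CPM and EOMES from 22.5 ± 2.12 to 111 ± 29.7 CPM. Among midbrain and hindbrain genes 10 of 11 fell (10 over the list alone, camera adjusted p = 1.5e-11). Dorsal telencephalon genes passed upward, as 8 rose, 2 fell and 5 did not pass (8 and 2 over the list alone, camera adjusted p = 0.00017), although their mean log2 change was -0.11. Radial glia genes rose, as 8 rose, 3 fell and 10 did not pass (9 and 4 over the list alone, camera adjusted p = 0.0014). SOX2 went from 95.6 ± 19.9 to 223 ± 65.4 CPM. Of the p53 targets 14 of 16 rose (14 over the list alone, camera adjusted p = 3.3e-12), and of the hypoxia and glycolysis genes 15 of 16 rose (15 over the list alone, camera adjusted p = 5.5e-16). HES1 rose from 35.6 ± 6.94 to 118 ± 22.6 CPM and AXIN2 fell from 42.3 ± 4.79 to 5.91 ± 1.41 CPM. MKI67 did not pass (adjusted p = 0.44). G2/M genes showed no shift, as 9 rose, 7 fell and 36 did not pass (8 and 6 over the list alone, camera adjusted p = 0.81). The counts were 6 rising and 8 falling without replicate 1 of DIV174 CHIR+DAPT, a choice made after its values were seen, and 8 rising and 12 falling with no filter on low counts.

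The interaction of DAPT and day compares the DAPT effect in CHIR at DIV174 and DIV50. It differed for 852 genes, 444 with a higher and 408 with a lower effect at DIV174 (1368 by DESeq2). Run and time in DAPT may also differ by day. Of 52 G2/M genes, 39 had a higher DAPT effect at DIV174, 0 a lower one and 13 did not pass (47 and 0 over the list alone, camera adjusted p = 1.3e-66). TOP2A, which untangles replicated DNA, went from 655 ± 35.8 to 235 ± 42.9 CPM with DAPT at DIV50 and from 239 ± 54.4 to 273 ± 49 CPM at DIV174 (difference 1.67 ± 0.20, adjusted p = 1.9e-05). NUF2, a kinetochore protein, differed likewise (1.90 ± 0.23, adjusted p = 1.9e-05). For the S-phase genes 4 of 43 differed, all with a higher effect at DIV174 (7 over the list alone, camera adjusted p = 0.00084, adjusted p = 0.52 with an estimated correlation). MKI67 did not pass (0.61 ± 0.19, adjusted p = 0.056, from 0.012 with no filter on low counts to 0.15 over the alternatives). Replication-dependent histones differed upward, with 4 of 14 passing (5 over the list alone, camera adjusted p = 5.3e-05). DLL1 fell with DAPT at DIV50 and rose at DIV174 (difference 1.04 ± 0.18, adjusted p = 0.00074). In the immature neuron list the effect was lower at DIV174 for 7 genes and higher for 1 of 24 (8 and 1 over the list alone, camera adjusted p = 1e-05, adjusted p = 0.29 with an estimated correlation). STMN2 (-0.25 ± 0.26, adjusted p = 0.66), DCX (adjusted p = 0.9) and HES5 (adjusted p = 0.68) showed no difference that passed. The largest differences were for VCAM1 (2.57 ± 0.45, adjusted p = 0.001), DEPDC1 (2.15 ± 0.27) and SCUBE1 (-2.49 ± 0.27).

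DAPT at DIV30, after 48 h on Lam511 with CHIR, shows the early response to Notch blockade. Fold changes were small: S-phase, G2/M and cortical hem genes fell. HES1 fell from 77.2 ± 4.53 to 53.4 ± 2.62 CPM (log2 change -0.53 ± 0.05, adjusted p = 1.8e-06) and DCX rose from 179 ± 3.46 to 226 ± 8.7 CPM (log2 change 0.34 ± 0.04, adjusted p = 1e-05), while STMN2 did not pass (adjusted p = 0.58). RSPO1, a secreted amplifier of Wnt signals, fell from 81 ± 5.87 to 35.5 ± 3.62 CPM and OLFML2B, a matrix protein, from 29 ± 3.08 to 10.6 ± 0.594 CPM. VGF, a neurotrophin-induced secreted protein, rose from 8.13 ± 1.13 to 15.3 ± 3.01 CPM and TTR from 33 ± 3.8 to 55.3 ± 7.76 CPM. In all, 1491 genes changed, 606 higher and 885 lower, of which 42 changed by at least 2-fold. The count was 980 without replicate 2 of the CHIR+DAPT group and 561 with transcript length offsets.

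Of the S-phase genes 33 of 43 fell (40 over the list alone, camera adjusted p = 6.4e-42). MCM4 went from 109 ± 4.08 to 84.2 ± 3.73 CPM, and of 52 G2/M genes 0 rose, 43 fell and 9 did not pass (1 and 46 over the list alone, camera adjusted p = 7.8e-47). MKI67 went from 321 ± 30.4 to 231 ± 23.1 CPM. Among 15 genes of the cortical hem, the Wnt source beside the hippocampus, 0 rose, 9 fell and 6 did not pass (1 and 10 over the list alone, camera adjusted p = 1.4e-14). WNT3A went from 2.96 ± 0.181 to 0.977 ± 0.202 CPM. Among Notch targets 5 of 12 fell (8 over the list alone, camera adjusted p = 1.2e-06, adjusted p = 0.12 with an estimated correlation). HES5 stood at 0.067 ± 0.0527 against 0.304 ± 0.0883 CPM. Proneural and intermediate progenitor genes moved up, as 5 of 20 rose (7 over the list alone, camera adjusted p = 0.0016, adjusted p = 0.12 with an estimated correlation). NEUROG1 stood at 1.8 ± 0.0151 against 0.861 ± 0.136 CPM and DLL1 rose from 8.13 ± 0.627 to 10.9 ± 0.161 CPM. Wnt targets moved down, as 2 rose, 5 fell and 12 did not pass (2 and 7 over the list alone, camera adjusted p = 0.0044, adjusted p = 0.069 with an estimated correlation). NKD1 went from 232 ± 5.27 to 189 ± 8.12 CPM. Cholesterol synthesis genes moved up, as 12 of 20 rose (16 over the list alone, camera adjusted p = 1.1e-10, adjusted p = 0.19 with an estimated correlation). The immature neuron list showed no shift, as 4 rose, 6 fell and 14 did not pass (6 and 6 over the list alone, camera adjusted p = 0.98). PROX1 did not pass (adjusted p = 0.46).

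On Msl the same comparison called 1383 genes, 587 higher and 796 lower, 66 of them by at least 2-fold. Notch targets and cell cycle genes fell here too. HES1 fell from 82.7 ± 2.52 to 47.6 ± 2.3 CPM (log2 change -0.80 ± 0.05, adjusted p = 6.9e-09), and HES5 stood at 0.0531 ± 0.0233 against 3.09 ± 0.448 CPM (adjusted p = 7.8e-09). NES, an intermediate filament of neural stem cells, fell from 1160 ± 31.7 to 690 ± 37.5 CPM. DLK1, a membrane protein related to Notch ligands, rose from 7.27 ± 0.533 to 19.1 ± 2.17 CPM (log2 change 1.39 ± 0.10, adjusted p = 3e-08), and the chemokine receptor CXCR4 fell from 219 ± 9.67 to 96.1 ± 5.23 CPM. Among Notch targets 8 of 12 fell (10 over the list alone, camera adjusted p = 6.2e-29). NRARP went from 15.7 ± 0.924 to 9.49 ± 0.587 CPM and DTX4 from 144 ± 1.49 to 113 ± 1.57 CPM. Of the S-phase genes 35 of 43 fell (38 over the list alone, camera adjusted p = 1.2e-50) and of the G2/M genes 40 of 52 fell (44 over the list alone, camera adjusted p = 4.2e-53). MKI67 went from 318 ± 9.7 to 240 ± 14.7 CPM (adjusted p = 0.0095, and 0.051 without replicate 3 of CHIR+DAPT). Replication-dependent histones fell, as 13 of 14 fell (14 over the list alone, camera adjusted p = 3.1e-32). H1-5 went from 187 ± 5.52 to 126 ± 2.57 CPM. Of 15 cortical hem genes 1 rose, 7 fell and 7 did not pass (1 and 7 over the list alone, camera adjusted p = 3.1e-11). Of 19 Wnt targets 1 rose, 7 fell and 11 did not pass (2 and 8 over the list alone, camera adjusted p = 2.4e-05). AXIN2 went from 235 ± 10.1 to 206 ± 6.71 CPM (adjusted p up to 0.1 over the alternatives, with length offsets). Of 22 radial glia genes, 4 rose, 7 fell and 11 did not pass (5 and 7 over the list alone, camera adjusted p = 5.9e-06). DCX rose from 131 ± 1.83 to 173 ± 6.83 CPM, while neither STMN2 (adjusted p = 0.5) nor PROX1 (17.8 ± 1.19 against 15.5 ± 0.28 CPM, adjusted p = 0.15) passed. The count was 902 without replicate 1 of the CHIR group and 551 with length offsets, under which 32.1% rather than 42.4% of the called genes were higher.

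**Figure D3:**
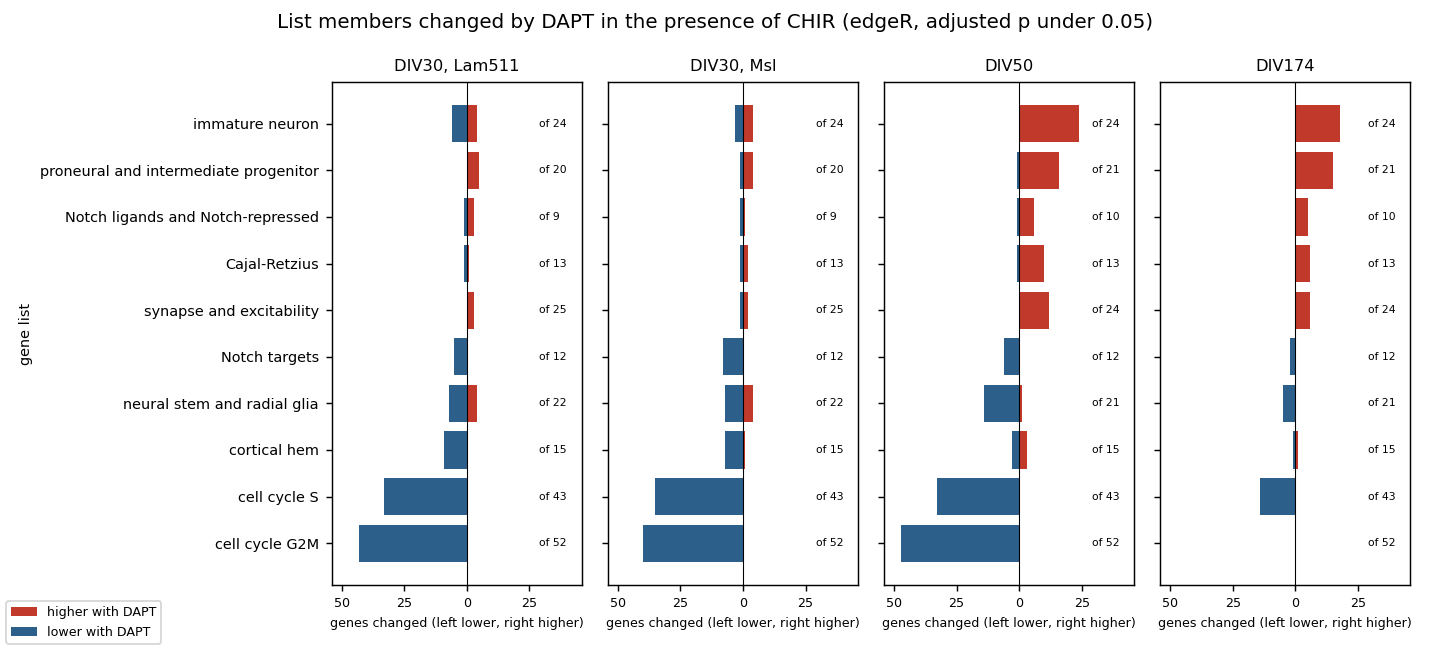
Number of genes of 10 lists that were higher (right, red) or lower (left, blue) with DAPT in the presence of CHIR at DIV30 on each coating, DIV50 and DIV174, beside the number measured. Of 52 G2/M genes, 43 and 40 fell at DIV30, 47 at DIV50 and 0 at DIV174. DIV30 also differs in kit.

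The interaction of DAPT and coating at DIV30 called 13 genes, 3 with a more positive and 10 with a more negative DAPT effect on Msl. In all, 1140 had an unadjusted p under 0.05. GRIP2, a scaffold of glutamate receptors, was 17.7 CPM in CHIR and 21.1 in CHIR+DAPT on Lam511, and 18 and 12.3 CPM on Msl (difference -0.80 ± 0.09, adjusted p = 0.00079). The kinase gene MAPK4 fell more on Msl (-0.64 ± 0.08, adjusted p = 0.0015), as did NES (-0.41 ± 0.07, adjusted p = 0.047, and up to 0.36 over the alternatives). Neither HES5 (-3.63 ± 0.75, adjusted p = 0.11, from 0.014 with no filter on low counts to 0.71 over the alternatives) nor HES1 (-0.26 ± 0.07, adjusted p = 0.33) passed. As a list the Notch targets had a lower effect on Msl, with 1 of 12 passing (7 over the list alone, camera adjusted p = 2.2e-08, adjusted p = 0.27 with an estimated correlation). DESeq2 called 43, no filter on low counts gave 45, length offsets 3, a replicate block 6, and the libraries left out gave 4 to 18. Leaving out replicate 2 or 3 of CHIR+DAPT on Lam511 (6, 5), replicate 1 or 2 of CHIR+DAPT on Msl (5, 4) or any replicate of CHIR on Msl (6, 4, 6) moved the count by more than 1.5 times and ended the call of NES. The share higher was 23.1%, 9.1% with DESeq2 size factors in edgeR, 44.2% with DESeq2 and 0% with length offsets.

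The coating itself was compared on Msl against Lam511 in CHIR. It changed 5343 genes, 2483 higher and 2860 lower, more than DAPT did on either coating. CALB1, a calcium-binding protein, stood at 115 ± 9.68 against 20.9 ± 2.37 CPM (log2 change 2.47 ± 0.11, adjusted p = 2.9e-08) and PROX1 at 15.5 ± 0.28 against 5.88 ± 0.559 CPM (log2 change 1.40 ± 0.09, adjusted p = 4e-10). The dentate granule lineage list showed no shift, as 6 rose, 6 fell and 3 did not pass (6 and 6 over the list alone, camera adjusted p = 0.53). SCG2, a secretory granule protein, stood at 46.9 ± 2.62 against 12.9 ± 2.17 CPM and HES5 at 3.09 ± 0.448 against 0.304 ± 0.0883 CPM (adjusted p = 3.3e-08). NPR3, a clearance receptor for natriuretic peptides, stood at 8.05 ± 2.16 against 83.2 ± 7.61 CPM (log2 change -3.36 ± 0.27, adjusted p = 2.1e-05), endothelin EDN1 at 9.31 ± 2.24 against 73.1 ± 5.19 CPM and ANKRD1 at 5.66 ± 1.55 against 34.2 ± 1.59 CPM. With transcript length offsets 3412 genes passed.

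**Figure D4:**
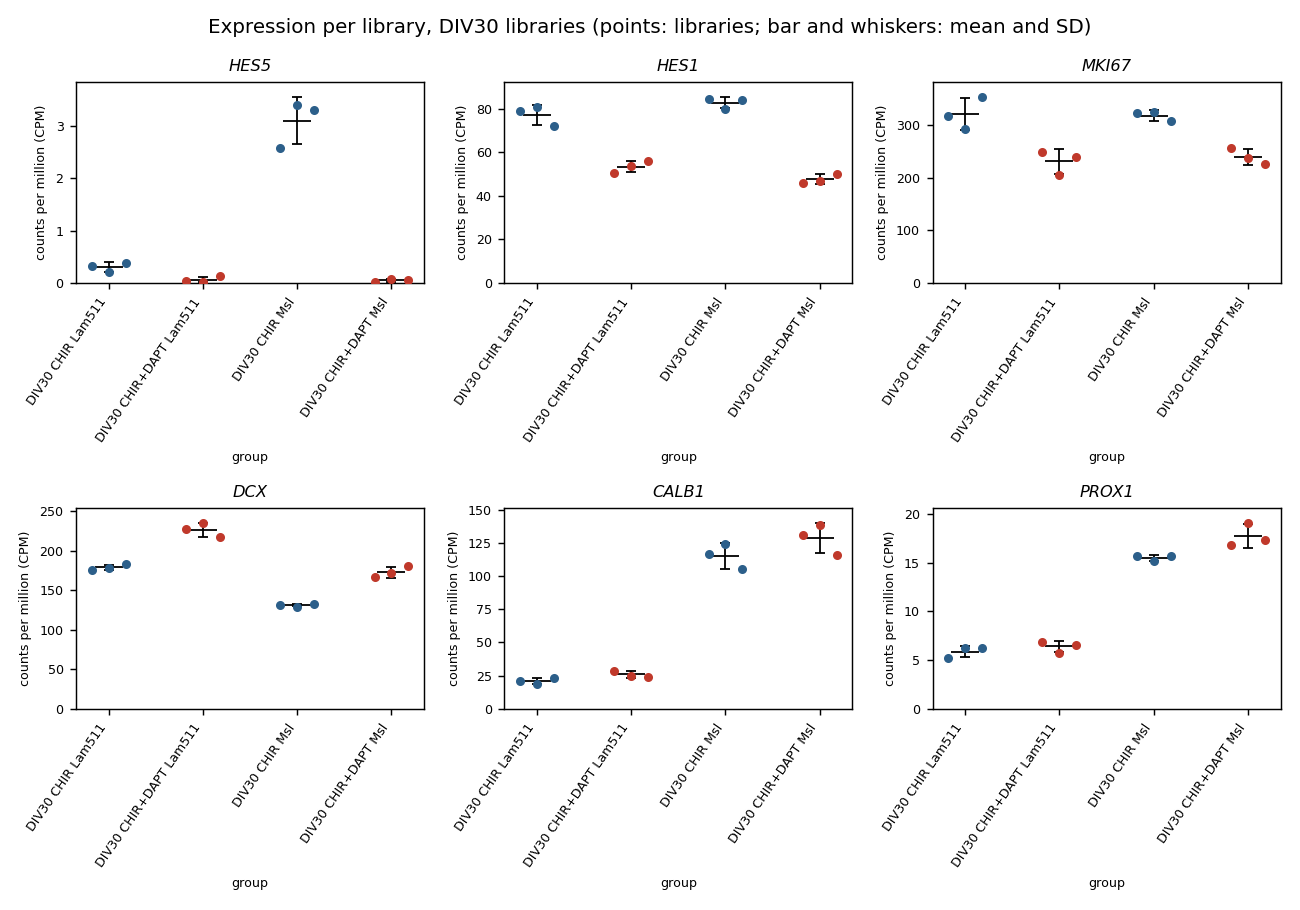
CPM of 6 genes in each of the 12 DIV30 libraries, by coating and factors (points, libraries; bar and whiskers, mean and SD; red, groups with DAPT; blue, groups without). CALB1 averaged 115 and 129 CPM on Msl against 20.9 and 25.9 CPM on Lam511, and HES1 averaged 53.4 and 47.6 CPM with DAPT against 77.2 and 82.7 CPM without.

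Of 21 targets of YAP and SRF, 2 rose, 19 fell and 0 did not pass (2 and 19 over the list alone, camera adjusted p = 8e-33, adjusted p = 0.082 with an estimated correlation). The myosin light chain MYL9 stood at 35.4 ± 0.709 against 71.9 ± 2.3 CPM and LATS2 at 58.7 ± 3.94 against 118 ± 4.85 CPM. Among cholesterol synthesis genes 18 of 20 fell (18 over the list alone, camera adjusted p = 2.6e-10, adjusted p = 0.22 with an estimated correlation). In the synapse and excitability list 15 rose, 1 fell and 9 did not pass (16 and 1 over the list alone, camera adjusted p = 0.00014, adjusted p = 0.082 with an estimated correlation). In the dorsal telencephalon list 10 rose, 1 fell and 4 did not pass (12 and 1 over the list alone, camera adjusted p = 0.00027, adjusted p = 0.22 with an estimated correlation). Of 24 immature neuron genes 11 rose, 6 fell and 7 did not pass (12 and 6 over the list alone, camera adjusted p = 0.019, adjusted p = 0.22 with an estimated correlation), DCX among the falls (131 ± 1.83 against 179 ± 3.46 CPM). Among 19 Wnt targets 11 rose, 4 fell and 4 did not pass (11 and 4 over the list alone, camera adjusted p = 0.00085, adjusted p = 0.082 with an estimated correlation). LEF1 stood at 99.2 ± 2.35 against 77.4 ± 5.42 CPM, AXIN2 at 235 ± 10.1 against 198 ± 4.91 CPM and APCDD1, a Wnt inhibitor, at 125 ± 2.95 against 59.7 ± 1.45 CPM. In the laminin and basement membrane list 4 rose, 12 fell and 2 did not pass (4 and 13 over the list alone, camera adjusted p = 0.0097, adjusted p = 0.44 with an estimated correlation). Collagen COL4A1 stood at 89.4 ± 4.82 against 180 ± 17.1 CPM. Notch targets were higher, as 7 rose, 0 fell and 5 did not pass (7 and 1 over the list alone, camera adjusted p = 0.0025, adjusted p = 0.29 with an estimated correlation). SOX2 stood at 241 ± 6.31 against 170 ± 14 CPM. MKI67 did not pass (adjusted p = 0.93).

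In CHIR+DAPT the coating changed 5329 genes, 2541 higher and 2788 lower (3416 with transcript length offsets). CALB1 stood at 129 ± 11.4 against 25.9 ± 2.41 CPM on Msl and Lam511 (log2 change 2.31 ± 0.10, adjusted p = 4.4e-08) and PROX1 at 17.8 ± 1.19 against 6.41 ± 0.59 CPM (log2 change 1.47 ± 0.08, adjusted p = 2.2e-10). The dentate granule lineage list again showed no shift, as 7 rose, 6 fell and 2 did not pass (7 and 6 over the list alone, camera adjusted p = 0.56). The stress neuropeptide gene CRH stood at 31.3 ± 1.03 against 8.47 ± 0.895 CPM. NPR3 was lower (11.1 ± 4.65 against 92.6 ± 8.49 CPM, log2 change -3.04 ± 0.26, adjusted p = 3.3e-05), and HES5 did not pass (adjusted p = 0.81). Of 21 targets of YAP and SRF, 19 of 21 fell (20 over the list alone, camera adjusted p = 6.4e-36, adjusted p = 0.087 with an estimated correlation). MYL9 stood at 33.7 ± 3.36 against 71.7 ± 4.24 CPM. Cholesterol synthesis genes were lower, as 17 of 20 fell (17 over the list alone, camera adjusted p = 1.2e-08, adjusted p = 0.27 with an estimated correlation). In the synapse and excitability list 17 rose, 1 fell and 7 did not pass (19 and 1 over the list alone, camera adjusted p = 1.8e-05, adjusted p = 0.086 with an estimated correlation). Of 19 Wnt targets 11 rose, 4 fell and 4 did not pass (11 and 4 over the list alone, camera adjusted p = 0.0061, adjusted p = 0.098 with an estimated correlation). LEF1 stood at 92.3 ± 1.85 against 68.6 ± 0.397 CPM. Of 18 laminin and basement membrane genes 3 rose, 11 fell and 4 did not pass (3 and 11 over the list alone, camera adjusted p = 0.00073, adjusted p = 0.28 with an estimated correlation). None of the 14 list calls for the coating in CHIR, nor the 14 in CHIR+DAPT, held with an estimated correlation.

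Across genes, the log2 changes with DAPT in CHIR were compared between days and coatings in 6 pairs, with the caution that genes are not independent replicates. Spearman's rho was 0.407 between Lam511 and Msl at DIV30, 0.256 between DIV50 and DIV174, 0.125 between Lam511 and DIV50, 0.162 between Msl and DIV50, 0.046 between Lam511 and DIV174 and 0.113 between Msl and DIV174. Among genes with a mean of at least 3 log2 CPM in both, the values were 0.587, 0.432, 0.194, 0.237, 0.091 and 0.207 in that order. DIV50 and DIV174 shared 378 genes higher with DAPT where 66.6 were expected (Fisher's exact test, two-sided, p = 1.3e-222) and 189 lower where 35.1 were expected (p = 3.6e-98), and 24 genes went opposite ways. Lam511 and Msl shared 280 higher (20.4 expected, p = 2.6e-269) and 485 lower genes (40.5 expected) by the same exact test, with 2 opposite. Lam511 and DIV50 shared 158 higher and 308 lower genes (78.1 and 99.4 expected), while 152 went opposite ways, and Msl and DIV50 shared 159 and 330 (75.2 and 89.1 expected) with 145 opposite. Lam511 and DIV174 shared 51 higher and 65 lower genes (20.0 and 17.8 expected) with 41 opposite, and Msl and DIV174 shared 59 and 79 (19.3 and 15.9 expected) with 41 opposite.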

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

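The tests of cycling at DIV174 before DAPT, of a different differentiation run and of a hidden 2-fold rise of Wnt targets were chosen after the results were seen. The effect of DAPT in CHIR differed between DIV174 and DIV50 for 852 genes by the interaction test. As lists, the G2/M genes and the replication-dependent histones (adjusted p = 0.0035 each with an estimated correlation) differed upward. DLL1 differed by 1.04 log2. The interaction of CHIR and DAPT at DIV50 differed downward for the replication-dependent histones as a list (adjusted p = 0.0066 with an estimated correlation), and the interaction of DAPT and coating at DIV30 called 13 genes. Both histone results come from the poly(A) kit, whose capture of histone transcripts was not tested.

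G2/M genes fell with DAPT at DIV50, 47 of 52, and 0 fell at DIV174. Leaving out the DIV174 CHIR+DAPT library that stands apart left 41 of the 52 with a more positive DAPT effect at DIV174, which argues against that library as the cause. Too few G2/M reads at DIV174 to show a fall is argued against by a median of 812.5 reads per gene and library. The median G2/M level in CHIR at DIV174 lay 0.05 log2 from the level that DAPT had brought about at DIV50, where its median effect was -1.26, against -0.08 at DIV174. Fewer cycling cells at DIV174 before DAPT might leave little to fall, a hypothesis found in these data. The S-phase genes go against such a floor: in CHIR at DIV174 they lay 0.09 log2 from the DIV50 CHIR+DAPT level, yet DAPT still lowered 14 of 43 (median effect -0.35, against -0.6 at DIV50). The explanation stays open, and the share of cycling cells itself was not analysed here.

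CHIR alone changed 11 genes at DIV50. Simulated libraries of this size recovered 68.7% of genes planted at 2-fold and 66.7% at 4-fold, so too little power with 3 libraries per group cannot be told apart from a small effect. Exchanged libraries are argued against, since the highest of the other 9 splits of the 6 libraries called 0 genes. A 2-fold rise of the Wnt targets that the spread hid is argued against for 14 of the 18 targets, whose 95% intervals end below 2-fold, and stays open for the 4 that reach it. Earlier CHIR medium, which by the protocol all groups of this day shared, may leave little further effect, which was not tested.

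Dorsal telencephalon genes were high at DIV28 and low at DIV50. Of the 13 dorsal telencephalon genes that were lower at DIV50, 9 were higher again at DIV174 in CHIR, which may reflect a different run of differentiation for each day. Run and day cannot be told apart, because the labels name no run.

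Other splits of the same libraries were counted for every comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the real split alone (1 of 10) gave as many genes in each of the 14 comparisons of 2 groups. The real counts and the highest of the other splits were 9645 and 1 for DIV28 against hiPSC, 6807 and 0 for DIV50 against DIV28, and 11 and 0 for CHIR at DIV50. For DAPT at DIV50 they were 3881 and 1, for both factors against none 4461 and 0, for DAPT in CHIR 4005 and 0, and for CHIR in DAPT 83 and 0. At DIV174 they were 877 and 101 for DAPT in CHIR, 6916 and 0 against DIV50 in CHIR, and 6535 and 1 in CHIR+DAPT. At DIV30 they were 1491 and 1 for DAPT on Lam511, 1383 and 2 for DAPT on Msl, and 5343 and 0, and 5329 and 0, for the coating in CHIR and in CHIR+DAPT.

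For the interactions, splits were drawn from 200 possible ones. For CHIR and DAPT at DIV50 the real count was 0, which every split reaches, so this test is void. For DAPT and day 5 of 40 gave at least 852, up to 3755, so chance was not excluded by this share. Those many calls point to a structure of the samples: the 4 other splits as large for DAPT and day kept 1 day's DAPT labels whole and so carried that day's effect, and the highest count without that was 3. For DAPT and coating 5 of 100 splits gave at least 13, up to 194, so chance was not excluded, and the 4 others kept 1 coating's labels whole, with 1 as the highest without that.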

How the results depend on the processing

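Of the tests in this part, the list counts without replicate 1 of DIV174 CHIR+DAPT were chosen after the data were seen, and the others before. All 17 counts stayed within 1.5 times with DESeq2 size factors in edgeR and with the stricter filter, and 16 of 17 with a replicate block. DESeq2 kept 12 of 17 within that bound, length offsets 10, no filter on low counts 13, only the groups compared in the fit 14, and leaving out 1 library 95 of 120.

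With DESeq2 the counts that moved further were 51 for CHIR against no factor at DIV50 (11 as reported), 218 for CHIR+DAPT against DAPT (83), 10 for the CHIR by DAPT interaction (0), 1368 for DAPT by day (852) and 43 for DAPT by coating (13). With length offsets they were 3 and 35 for the first pair, 561 and 551 for DAPT at DIV30 on Lam511 and Msl (1491 and 1383), 3412 and 3416 for the coating in CHIR and CHIR+DAPT (5343 and 5329), and 3 for DAPT by coating. Without a filter they were 220, 397, 84 for the CHIR by DAPT interaction, and 45 for DAPT by coating. With only the groups compared in the fit they were 216, 304, and 227 for DAPT at DIV174 (877). A replicate block gave 6 for DAPT by coating. Leaving out 1 library gave 0 to 1 for CHIR against no factor, 21 to 47 for CHIR+DAPT against DAPT, 0 to 1 for the CHIR by DAPT interaction, 574 to 970 for DAPT at DIV174, 980 to 1761 on Lam511, 902 to 1175 on Msl and 4 to 18 for DAPT by coating. Fewer libraries explain part of a lower count. The cause of the other differences was not tested.

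With an estimated correlation 109 of the 241 list calls held, and with fry 204 of them, and none turned direction. Of 463 list and comparison pairs with a called gene, 23 had the majority of calls turn under an alternative, among them the G2/M genes at DIV50 against DIV28. The rank correlations of DAPT effects rose from 0.407, 0.125, 0.046, 0.162, 0.113 and 0.256 to 0.587, 0.194, 0.091, 0.237, 0.207 and 0.432 among genes with at least 3 log2 CPM, in the order Lam511 with Msl, DIV50 and DIV174, Msl with DIV50 and DIV174, and DIV50 with DIV174.

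Of 236 pairs of a named gene and a comparison, 196 were called, 178 of these kept direction and call in all alternatives, and 18 lost the call in at least 1, of which 7 did so only with a library left out. Among those not called, 9 passed in at least 1 alternative. No call turned direction. Replicate numbers were not treated as pairs: 16 of 24 poly(A) and 2 of 12 ribosomal RNA-depleted libraries were closest to libraries with their own number, and 0 of 19 pairs of groups had every paired correlation above 0.1. Depth limits genes near 0 reads, such as HES5 with DAPT at DIV30 (0.067 and 0.0531 CPM).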

Other observations

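The genes of this part were chosen after their values were seen, and no tests were added for them. Among the poly(A) groups, several transcription factors of the dorsal midbrain, hindbrain and spinal cord were highest at DIV50. PAX7 stood at 23.5 ± 1.55 CPM (n = 3) at DIV50 without factors and at 0 at DIV28 and in both DIV174 groups. LMX1B stood at 42.1 ± 0.868 CPM in DIV50 CHIR+DAPT, 7.74 ± 0.856 CPM in DIV50 CHIR and 0.140 ± 0.111 CPM in DIV174 CHIR. POU4F1 stood at 125 ± 8.07 CPM in DIV50 CHIR+DAPT and 13.2 ± 3.79 CPM in DIV174 CHIR+DAPT. Of 39 HOX genes in the annotation, which pattern the hindbrain and spinal cord, 1 had enough reads to be tested, and the highest group mean was 0.747 CPM, for HOXB2 in DIV50 DAPT.

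OTX2, a gene of the forebrain and midbrain, stood at 142 ± 31.1 CPM in hiPSC, 56.9 ± 4.60 CPM at DIV28, 87.6 ± 1.77 CPM at DIV50 without factors and 85.0 ± 3.33 CPM in DIV174 CHIR. SIX3 and RAX, genes of the anterior forebrain and eye field, stood at 289 ± 31.6 and 26.8 ± 4.50 CPM in DIV174 CHIR against 27.3 ± 3.23 and 1.33 ± 0.273 CPM in DIV50 CHIR. PDGFRA, a receptor of oligodendrocyte progenitors, stood at 49.0 ± 3.30 CPM in DIV174 CHIR and 39.5 ± 6.62 CPM in DIV174 CHIR+DAPT against 1.53 ± 0.587 CPM in DIV50 CHIR. Mitochondrial genes took 0.604% ± 0.122 (SD, n = 3) of the reads in DIV174 CHIR and 2.62% ± 0.305 in DIV50 CHIR.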
